A study of Homo sapiens with 2 samples.

How the data were processed

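The data are single-nucleus gene expression counts from 2 samples of human dorsal root ganglia, 1 library each. Per the labels' protocols, nuclei were released from microdissected tissue by homogenisation, purified by ultracentrifugation through sucrose, captured with the 10x Genomics 3' chemistry (version 3.1) and sequenced on an MGISEQ-2000. The deposited values are raw counts of UMIs per gene and barcode, and per the file headers they were written by Cell Ranger 7.2.0. The submitters' processing notes list the genome build GRCh38, Seurat 4.3.0 and R 4.3.0, without saying what each was used for. The lowest total of a barcode in either library was 500 UMIs, and the filters on barcodes before deposit are not given in the sources used here. Both libraries belong to 1 group, so they are replicates, and classes of nuclei were compared within them.

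Of 36601 genes, 132 that are sex-linked were left out of all steps. Barcodes needed at least 300 detected genes and a mitochondrial share under 5%, which removed 1 and 358 barcodes. Doublets were called per library by simulating pairs and ranking nuclei by their share of simulated neighbours, at an assumed 0.8% per 1000 nuclei. The called doublets, 514 (6.41%) and 87 (2.64%), were removed; their medians were 4173.5 and 4113 UMIs. Log-normalised values of 2000 variable genes were scaled within each library, reduced to 30 principal components and clustered with the Leiden method on a graph of 20 neighbours (scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Python 3.11.15). The clustering split neurons from other nuclei at resolution 1 and then clustered the non-neuronal nuclei again at 1.5 and the neurons at 1. Genes of the lists tested below were kept out of the clustering features, 561 features with the mitochondrial genes, so that classes were not formed on the genes compared. Free RNA was not subtracted.

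Clusters were named from 20 lists with 136 marker genes fixed before the data were examined, and neuron clusters from 5 lists with 28 genes. A non-neuronal cluster was named where at least 3 markers and the majority of a list were raised 1.5-fold over the median cluster. A later pass set the clusters left over against the mean of those already named. Clusters stayed unnamed with leading genes of another list, raised markers of 2 lists, or a high share of ribosomal protein transcripts. Neuron clusters met a looser rule: at least 3 markers of a list above the median neuron cluster, with no fold or majority required. They stayed unnamed where at least 6 of their 10 leading genes were higher in non-neuronal nuclei. The names say which markers a cluster resembles. Several choices were made with class sizes and marker levels in view, before any test. These were log-normalised values in place of Pearson residuals, the non-neuronal resolution among 9 tried, the naming rule among about 4 versions, the naming fold of its later pass, and the omission of 5 neuron markers (NEFL, NEFM, NEFH, STMN2 and UCHL1) that were high outside neurons too. Of the 9 resolutions, 3 gave at least 20 mural-like nuclei in both libraries, and 1.5 was taken because its mural-like cluster was clean.

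Raw counts were summed per class and library where at least 20 nuclei were present. The fit of all classes held 14 sums of 7 classes, from 31417 to 26149184 UMIs, with 12734 genes and 6 residual degrees of freedom. The fit of neuron sub-classes held 8 sums of 4 classes with 14289 genes and 3 residual degrees of freedom; cold-sensing-like neurons (29 and 10 nuclei) were too few. edgeR 4.0.16 (R 4.3.3) was used with TMM scaling, its default filter on low counts, robust quasi-likelihood dispersions and two-sided quasi-likelihood tests. Adjusted p-values are Benjamini-Hochberg over all genes of a fit, with a threshold of 0.05. The library was a block, since sums with the same library number come from the same sample. A class set against several others was set against their unweighted mean. Log2 folds are fitted values, and the SE is the absolute fold over the square root of the test's F. Folds in 1 library alone are not fitted. They are differences of log2 CPM with a prior count of 2, averaged over classes where several are meant. CPM of single genes were computed within each sum, with its total multiplied by its TMM factor, and averaged over classes where several are meant. In the fit of all classes these factors were 0.7448 and 0.7554 for neuron-like nuclei of libraries 1 and 2. For mural-like nuclei they were 1.3372 and 1.3423. CPM summed over cholesterol synthesis genes were taken over all UMIs of the nuclei without TMM factors, so the 2 kinds of CPM are on different scales. Where a class of the second group had no count, or where 1 library's sum was at 0 in a comparison of 2 classes, the fitted fold depends on the prior count and CPM are given instead.

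Comparisons are reported only for genes of 23 lists with 549 genes, fixed before the data were examined. They cover ion channels, receptors, ligands, glial, matrix, vascular, immune and stress genes. Levels of a few other genes are given without a test. Each list was tested with camera (limma 3.58.1), two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Of 114 list tests in the planned comparisons, 40 were called with the preset and 12 with an estimated correlation, all 12 among the 40. Genes were named by a rule fixed before the data were examined. In lists with at least 2 called genes, up to 3 highest and 2 lowest called genes with the same direction in both libraries were taken, lists in order of calls until 30 genes, with the most abundant member that did not pass; markers of a class compared were left out. Some genes that the rule names are not reported here. Coordinates are those of GRCh38 in the GENCODE annotation.

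Each comparison was tested on simulated data with 200 changed genes, all drawn from genes above the median abundance of the fit. No other gene differed between classes, unlike in the data. The shares recovered therefore do not cover genes with low counts, and the shares of false calls hold for this setting. With each gene's own dispersion, 4-fold changes were recovered for 100% of genes in the neuron-like and macrophage-like comparisons, 98% in A-fibre-like, 96% in fibroblast-like, 85% in satellite glia-like and 60% in endothelial-like against mural-like nuclei. For 2-fold changes these shares were 70%, 54%, 38%, 49%, 12% and 9%. False calls made up 8.8% to 15.4% of calls over all comparisons with each gene's own dispersion, above the nominal 5%, and 2.05% to 7.81% with 1 dispersion for all genes. Calls near the threshold are therefore less certain than their adjusted p. The libraries shared 5 barcodes.

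Alternatives fixed before the data were examined were median-of-ratios size factors, DESeq2 1.42.0, no filter on low counts, no library term, 0.5 and 2 times the resolution, doublets kept, at least 600 genes, classes and tests on separate random parts of the counts, each library alone, other scalings for clustering and a mitochondrial limit of 10%. Added after the data were seen were nuclei with at least 2000 UMIs, a lower naming fold, neuron-like nuclei without clusters led by genes of other classes, fits without mural-like sums, and 3 comparisons: satellite glia-like against myelinating Schwann-like, pruriceptor-like against nociceptor-like and endothelial-like against the other classes. The planned comparisons with non-myelinating Schwann-like nuclei were left out because no cluster took that name at the resolution and naming fold taken with class sizes in view. Of the 9 resolutions tried, 6 gave such clusters, and so did the lower naming fold at the resolution taken. Figures were drawn with matplotlib 3.10.9.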

Results

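Single-nucleus RNA sequencing was performed on 2 samples of human dorsal root ganglia. These are the clusters beside the spinal cord that hold the cell bodies of sensory neurons together with their glia, vessels and immune cells. Each sample gave 1 library, and the labels place both in 1 group, so the comparisons are between cell classes within the 2 libraries. Library 1 held 8278 barcodes with 51645337 unique molecular identifiers (UMIs), and library 2 held 3392 barcodes with 9266897 UMIs. After filtering, 7502 and 3208 nuclei remained, with medians of 1946 and 1334.5 UMIs. The labels do not say that the samples came from separate donors, and the sample titles do not say how many ganglia each holds. With the library as a block, p-values rest on how far class differences varied between these 2 samples, pooled over classes. That spread may be technical. The libraries are not copies of 1 library: of 16598 genes with at least 100 counts over both libraries, 2394 (14.4%) were more than 2-fold apart, with 133 for chi-square per degree of freedom.

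The nuclei fell into 7 classes named from fixed markers, with shares that depend on the clustering. Neuron-like nuclei made up 13.1% ± 1.42 of nuclei (SD, n = 2 libraries; mean 8.18% without clusters led by genes of other classes), endothelial-like nuclei 12.5% ± 0.05, macrophage-like nuclei 11.3% ± 3.58 and fibroblast-like nuclei 8.52% ± 0.55. The fibroblast-like share was 2.89% and 6.67% in libraries 1 and 2 at 2 times the resolution, and no such class was named with genes scaled over all nuclei. That scaling also gave 0 macrophage-like nuclei in library 1 and 14.99% in library 2, and 0.29% and 35.3% mural-like nuclei. Myelinating Schwann-like nuclei, the glia that wrap large axons, made up 2.92% ± 1.00 and mural-like nuclei, the contractile cells of vessel walls, 0.54% ± 0.16 (none named at 0.5 times the resolution). Satellite glia-like nuclei, the glia that surround neuron cell bodies, made up 13.8% (exact binomial 95% interval 13.1 to 14.6) of library 1 and 1.96% (1.51 to 2.51) of library 2. Library 1 was higher in every setting, by an amount that depends on the setting. The shares were 39.9% and 14.5% at 0.5 times the resolution, 19.7% and 4.42% with a mitochondrial limit of 10%, 22.0% and 15.1% with a lower naming fold and 33.32% and 26.98% at 600 or more genes per nucleus. Macrophage-like nuclei made up 8.74% (8.11 to 9.41) and 13.8% (12.6 to 15.1). The intervals cover counting error only. The libraries are replicates of 1 group and were not compared by a test.

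Nuclei without a name made up 40.5% (39.4 to 41.6) of library 1 and 45.8% (44.1 to 47.5) of library 2, because thresholds of the naming rule set with the class sizes in view kept 6 clusters out of every class. In libraries 1 and 2 these clusters held 11.9% and 19.6% of nuclei (cluster 1, median 984 and 627 UMIs), 16.6% and 7.89% (cluster 2), 8.08% and 2.99% (cluster 6), 3.80% and 3.99% (cluster 9), 0.093% and 10.1% (cluster 11), and 0.04% and 1.22% (cluster 16). Cluster 9 was set aside for its high share of ribosomal protein transcripts. The larger macrophage-like cluster was led by the T cell gene THEMIS and by IKZF1 beside CD163, the smaller by CSF1R, TNFRSF1B and SRGN, and SLC2A1, a marker of perineurial cells, was among the genes leading the fibroblast-like cluster. Neuron-like nuclei had median depths of 9227 and 2440 UMIs and satellite glia-like nuclei of 3995 and 1944, against 1386 to 1648 in library 1 and 1306 to 1444 in library 2 for the endothelial-like, macrophage-like, fibroblast-like and myelinating Schwann-like nuclei.

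**Figure D1:**
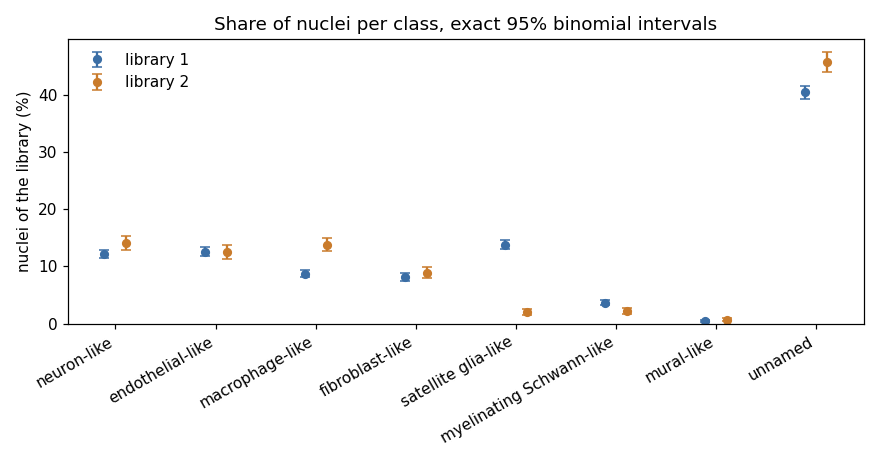
Share of nuclei (percent, vertical axis) in each class in libraries 1 and 2, with exact binomial 95% intervals as error bars. Satellite glia-like nuclei were at 13.8% in library 1 and 1.96% in library 2 in the setting drawn, and library 1 was higher in every setting.

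Sensory neurons were set against the cells around them by comparing neuron-like nuclei with the mean of the 6 non-neuronal classes. Neuron-like nuclei were higher in calcium channel genes and lower in immediate early, matrix and cytokine genes on the CPM scale. With the preset correlation only, they were also higher in other ion channel and transmitter receptor genes and lower in MHC class II and complement genes. Of 367 measured genes of the fixed lists, 142 were higher and 129 lower in neuron-like nuclei (n = 2 libraries). Voltage-gated sodium channels, which carry the upstroke of the action potential, were higher for 10 of 11 measured members (10 adjusted over the list alone; list test adjusted p = 6.38e-06, and adjusted p = 0.142 with an estimated correlation). Voltage-gated calcium channels were higher for 11 of 12 (12 adjusted over the list alone; adjusted p = 1.35e-08, and adjusted p = 0.0298 with an estimated correlation).

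Potassium and HCN channels were higher for 26 and lower for 4 of 36 measured members (28 and 4 adjusted over the list alone; list test adjusted p = 2.19e-06, and adjusted p = 0.17 with an estimated correlation). KCNB2, a delayed rectifier potassium channel (ENSG00000182674, chromosome 8, 72537391 to 72938349, GRCh38), was higher by 4.28 ± 0.37 on the log2 scale (SE, adjusted p = 1.15e-06), 2.94 in library 1 alone and 5.45 in library 2 alone. KCNK10, a background potassium channel also known as TREK-2, was at 115 and 136 CPM in neuron-like nuclei of libraries 1 and 2 against 12.9 and 9.32 in the other classes. KCNK13, a background potassium channel, fell by 2.33 ± 0.32, and KCNQ3, the most abundant member that did not pass, had 0.46 ± 0.21 (adjusted p = 0.0724; called in 2 other settings). Among genes chosen after their values were seen, SCN10A, the sodium channel Nav1.8 of nociceptors, was higher by 3.95 ± 0.28 (3.06 and 4.62 in libraries 1 and 2 alone) and CACNA1C, an L-type calcium channel, by 2.69 ± 0.20.

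Glutamate receptors were higher for 14 and lower for 2 of 19 measured members (14 and 2 adjusted over the list alone; list test adjusted p = 2.92e-05, and adjusted p = 0.142 with an estimated correlation). GRIK4, a kainate receptor subunit, was higher by 3.88 ± 0.23 (adjusted p = 1.51e-15), while GRIN2B, an NMDA receptor subunit, and GRIK3 fell by 3.01 ± 0.25 and 2.33 ± 0.24. GABA-A receptors were higher for 4 of 5 (4 adjusted over the list alone; adjusted p = 0.00166, and adjusted p = 0.142 with an estimated correlation). Sensory transduction channels were higher for 17 and lower for 4 of 26 (17 and 5 adjusted over the list alone; adjusted p = 0.00167, and adjusted p = 0.142 with an estimated correlation). P2RX3, an ATP-gated channel of sensory neurons, was higher by 3.41 ± 0.32 (2.73 in library 1 and 5.58 in library 2 alone), and TRPM8, the cold and menthol receptor, was at 36.9 and 44.7 CPM against 3.24 and 0.725. PIEZO1, a mechanically gated channel, fell by 2.85 ± 0.46, and TRPM7 had 0.04 ± 0.20 (adjusted p = 0.995).

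Genes of axo-glial adhesion were higher for 13 of 18 measured members (13 higher and 1 lower adjusted over the list alone; list test adjusted p = 6.99e-06, and adjusted p = 0.217 with an estimated correlation). Neurotrophic factors and receptors went both ways, with 14 higher and 9 lower of 25 (14 and 9 adjusted over the list alone; adjusted p = 0.149). NRG1, a growth factor on axons that acts on Schwann cells, was higher by 3.92 ± 0.28 (3.03 and 4.64 in libraries 1 and 2 alone). IGF1 fell by 3.26 ± 0.45 (-2.60 in library 2 alone), a call that ended on separate random parts of the counts (adjusted p = 0.995). ERBB4 had 0.26 ± 0.20 and was called in 1 other setting only. Targets of analgesic drugs were higher for 7 and lower for 4 of 12 (8 and 4 adjusted over the list alone; adjusted p = 0.344), axon regeneration genes for 5 and 7 of 15 (6 and 7; adjusted p = 0.63, median and mean above 0 and the test pointing down).

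Every measured immediate early gene, 11 of 11, was lower in neuron-like nuclei on the CPM scale (11 adjusted over the list alone; list test adjusted p = 7.08e-07, and adjusted p = 0.0298 with an estimated correlation). Per nucleus this did not hold in both libraries, since the median log2 ratio of UMIs per nucleus was 0.74 in library 1 and -1.53 in library 2. NR4A1, chosen after its values were seen, was at 5.75 and 13.7 CPM against 83.5 and 134, a log2 fold of -3.39 ± 0.34. Collagens and other matrix genes were lower for 23 and higher for 2 of 32 (23 and 2 adjusted over the list alone; adjusted p = 1.37e-09, and adjusted p = 0.0298 with an estimated correlation). COL27A1, a fibrillar collagen, fell by 3.55 ± 0.25 (adjusted p = 5.96e-14) and COL5A3 by 3.26 ± 0.25. The basement membrane collagens COL4A4 and COL4A3 were higher by 3.16 ± 0.27 (4.42 in library 2 alone) and 2.37 ± 0.32 (3.02 in library 1 alone), and LAMC1 had -0.26 ± 0.21. Cytokines and their receptors were lower for 14 and higher for 3 of 25 (15 and 3 adjusted over the list alone; adjusted p = 0.000344, and adjusted p = 0.0298 with an estimated correlation). TGFBR2, a TGF-beta receptor, fell by 3.25 ± 0.28 (-2.65 in library 2 alone), TGFBR1 was higher by 1.61 ± 0.23, and OSMR had 0.11 ± 0.22.

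Among the other lists, MHC class II genes were lower for 7 of 9 (8 adjusted over the list alone; list test adjusted p = 0.000581, and adjusted p = 0.131 with an estimated correlation) and complement genes for 9 of 16, with 2 higher (9 and 2 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.0607 with an estimated correlation). Contractile genes were lower for 9 and higher for 2 of 14 (9 and 2 adjusted over the list alone; adjusted p = 0.000522, and adjusted p = 0.153 with an estimated correlation). Heat shock genes were lower for 6 of 11 (6 adjusted over the list alone; adjusted p = 0.0241, and adjusted p = 0.343 with an estimated correlation), and tight junction and transport genes for 6 of 18, with 3 higher (6 and 3 adjusted over the list alone; adjusted p = 0.0241, and adjusted p = 0.131 with an estimated correlation). Neuron RNA outside neurons moved with this comparison: NEFL, a neurofilament gene, had a UMI in 85.3% and 47.9% of endothelial-like nuclei of libraries 1 and 2, against 90.5% and 57.9% of neuron-like nuclei. Neuron-like clusters led by genes of other classes, such as APOD, ITGAX and VWF, held 4.17% and 5.77% of all nuclei. These were 313 of 911 neuron-like nuclei in library 1 and 185 of 454 in library 2. They held 5.5% and 6.9% of the neuron-like UMIs, and without them 143 list genes were higher and 129 lower. Depths and values per nucleus given for neuron-like nuclei include these clusters. Without the library term 169 list genes were called.

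**Figure D2:**
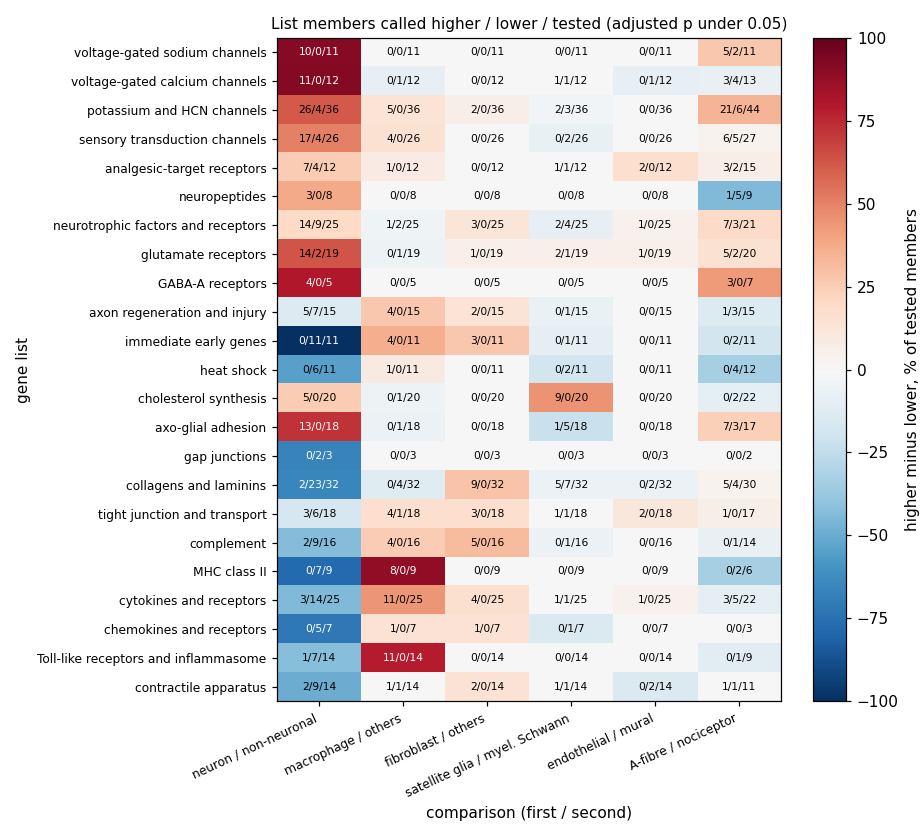
Genes called higher and lower and genes measured in each of 23 fixed lists (vertical axis) for 6 comparisons (horizontal axis), with colour for the percentage higher minus the percentage lower. In neuron-like nuclei 26 of 36 potassium and HCN channels were higher and 11 of 11 immediate early genes lower.

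Within the neurons, A-fibre-like nuclei, the neurons of large myelinated axons that serve touch and limb position, were set against nociceptor-like nuclei, which respond to harmful stimuli. The A-fibre-like class had 87 and 39 nuclei with median depths of 29657 and 6967 UMIs, the nociceptor-like class 158 and 103 nuclei with 43409.5 and 6225. With the preset correlation only, A-fibre-like nuclei were higher in potassium and sodium channel genes and lower in neuropeptide genes. Of 358 measured list genes, 72 were higher and 57 lower in A-fibre-like nuclei (n = 2 libraries). Potassium and HCN channels were higher for 21 and lower for 6 of 44 (21 and 8 adjusted over the list alone; list test adjusted p = 0.00475, and adjusted p = 0.577 with an estimated correlation).

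KCNA1, a low-threshold potassium channel of myelinated axons (ENSG00000111262, chromosome 12, 4909905 to 4918256, GRCh38), was at 49.3 and 49.2 CPM in A-fibre-like nuclei against 1.47 and 0 (adjusted p = 7.45e-10). KCND2, which carries a fast inactivating current, was higher by 3.87 ± 0.58 on the log2 scale (2.93 and 5.77 in libraries 1 and 2 alone). KCNT2, a sodium-activated potassium channel, fell by 4.16 ± 0.25 (adjusted p = 9.91e-13), and KCNB2 had 0.29 ± 0.21 (adjusted p = 0.392). Sodium channels were higher for 5 and lower for 2 of 11 (6 and 3 adjusted over the list alone; list test adjusted p = 0.0194, and adjusted p = 0.577 with an estimated correlation). Chosen after their values were seen, SCN1A was at 292 and 278 CPM against 7.33 and 7.95, a log2 fold of 5.29 ± 0.39, and SCN3B, an auxiliary subunit, fell by 2.86 ± 0.36.

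Neuropeptide genes were lower in A-fibre-like nuclei for 5 and higher for 1 of 9 measured members (5 and 2 adjusted over the list alone; list test adjusted p = 8.1e-06, and adjusted p = 0.29 with an estimated correlation). Chosen after their values were seen, ADCYAP1, which encodes the peptide PACAP, fell by 3.16 ± 0.29 (-2.41 in library 2 alone) and CALCB, a calcitonin gene-related peptide, by 2.01 ± 0.28 (-2.82 in library 2 alone). Calcium channels were higher for 3 and lower for 4 of 13 (4 and 5 adjusted over the list alone; adjusted p = 0.331), with CACNA1C, chosen in the same way, at -2.72 ± 0.21. Sensory transduction channels were higher for 6 and lower for 5 of 27 (6 and 7 adjusted over the list alone; adjusted p = 0.763, median below 0 and mean above 0). TRPA1, the receptor of mustard oil and other irritants, was at 7.42 and 0 CPM against 187 and 64.6 (adjusted p = 0.00211), and ANO1, a calcium-activated chloride channel, at 9.33 and 17.7 CPM against 0 and 0.993. PIEZO2, the touch channel, had 0.24 ± 0.82 (adjusted p = 0.905) and was not called.

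Neurotrophic factors and receptors were higher for 7 and lower for 3 of 21 (7 and 4 adjusted over the list alone; list test adjusted p = 0.23), among them GFRA1, a receptor of GDNF, by 3.48 ± 0.26 (adjusted p = 4.31e-11) and NRG1 by 2.09 ± 0.29 (adjusted p = 0.000138). NRG2 was not called (0.38 ± 0.22). Genes of axo-glial adhesion were higher for 7 and lower for 3 of 17 (7 and 3 adjusted over the list alone; adjusted p = 0.589). CADM2 and CNTN1, adhesion molecules of axons, were higher by 1.97 ± 0.23 and 1.51 ± 0.22, and CNTN2 fell by 1.46 ± 0.25. ANK2 had -0.30 ± 0.19. Collagens and other matrix genes were higher for 5 and lower for 4 of 30 (5 and 5 adjusted over the list alone; adjusted p = 0.99, median below 0 and mean above 0), led by LAMA3, a laminin chain, with 4.07 ± 0.33. LAMC1 had 0.38 ± 0.22. Glutamate receptors were higher for 5 and lower for 2 of 20 (6 and 3 adjusted over the list alone; adjusted p = 0.379). GABA-A receptors were higher for 3 of 7 (3 adjusted over the list alone; adjusted p = 0.145) and heat shock genes lower for 4 of 12 (4 adjusted over the list alone; adjusted p = 0.145). The call of GFRA1 ended at 0.5 times the clustering resolution (adjusted p = 0.0679), and 62 list genes were called without the library term.

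**Figure D3:**
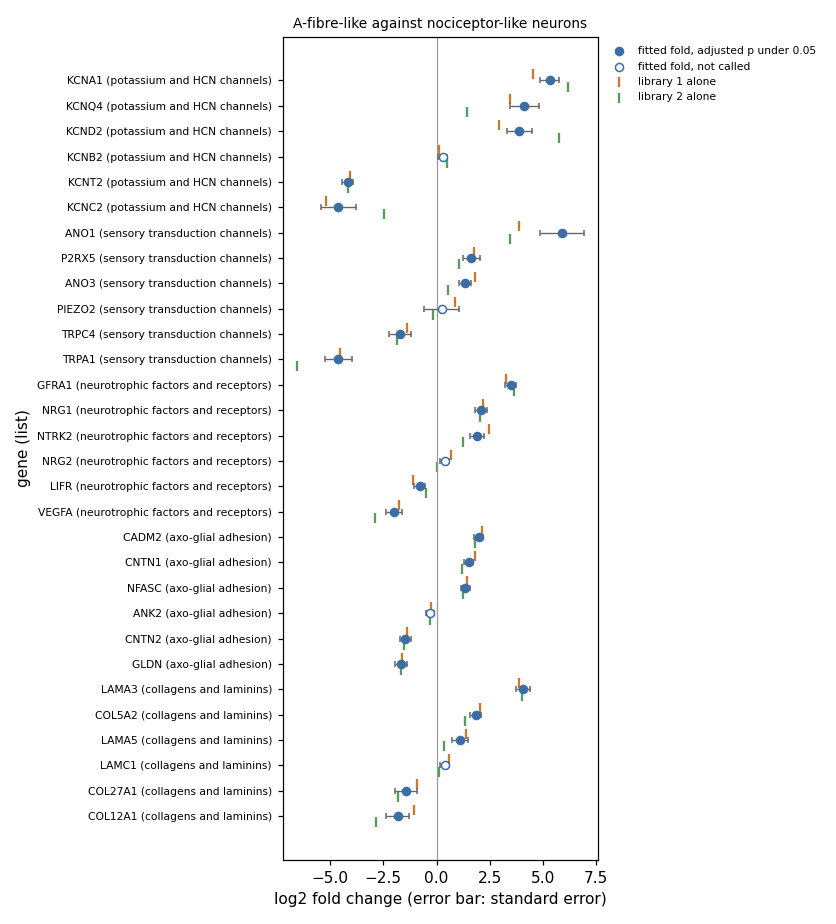
Log2 fold of named genes in A-fibre-like against nociceptor-like nuclei (horizontal axis) by list, with points for the fitted fold, bars for 1 SE, filled points for called genes and ticks for each library alone. LAMA3 lay at 4.07 and KCNT2 at -4.16, and the fitted folds of KCNA1, ANO1 and TRPA1 depend on the prior count because a sum of 1 class is at 0.

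Satellite glia-like nuclei were set against myelinating Schwann-like nuclei, to tell the glia around cell bodies from the glia along axons. This comparison was added after the classes were seen. The planned comparisons need a non-myelinating Schwann-like class, and the resolution and naming fold taken gave none. Of the 9 resolutions tried, 6 gave that class. At the resolution taken, the lower naming fold gave it 1246 and 253 nuclei in libraries 1 and 2. Satellite glia-like nuclei were higher in cholesterol synthesis genes and, with the preset correlation only, lower in genes of axo-glial adhesion. Of 367 measured list genes, 26 were higher and 33 lower in satellite glia-like nuclei (n = 2 libraries, with 1038 and 63 nuclei against 272 and 71). Cholesterol synthesis genes were higher for 9 of 20 (12 adjusted over the list alone; list test adjusted p = 4.91e-12, and adjusted p = 0.0116 with an estimated correlation).

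MVD, an enzyme of the mevalonate pathway (ENSG00000167508, chromosome 16, 88651935 to 88663161, GRCh38), was at 224 and 598 CPM in satellite glia-like nuclei against 65.7 and 103, a log2 fold of 2.08 ± 0.31 (adjusted p = 1.69e-05). FDPS, another enzyme of that pathway, chosen after its values were seen, was higher by 1.75 ± 0.33 (adjusted p = 0.000455). Genes of axo-glial adhesion were lower for 5 and higher for 1 of 18 (8 and 1 adjusted over the list alone; list test adjusted p = 5.23e-06, and adjusted p = 0.915 with an estimated correlation). GLDN, which encodes the nodal protein gliomedin, fell by 4.76 ± 0.43 (adjusted p = 6.37e-08; -4.06 in library 2 alone) and NFASC, neurofascin, by 4.05 ± 0.37. The member that was higher was CADM1 (adjusted p = 0.00265), a call that ended at 0.5 times the clustering resolution (adjusted p = 0.0859), and ANK2 had -0.10 ± 0.41.

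Collagens and other matrix genes went both ways in satellite glia-like nuclei, with 5 higher and 7 lower of 32 (7 and 8 adjusted over the list alone; list test adjusted p = 0.573). LAMA1, a laminin chain, was higher by 2.06 ± 0.30 and FN1, fibronectin, fell by 3.79 ± 0.36 (-3.05 in library 2 alone). LAMA2 had 0.53 ± 0.32. Neurotrophic factors and receptors were higher for 2 and lower for 4 of 25 (2 and 4 adjusted over the list alone), with ERBB3, a neuregulin receptor, higher by 1.27 ± 0.28. Potassium and HCN channels were higher for 2 and lower for 3 of 36 (2 and 4 adjusted over the list alone; adjusted p = 0.183), with KCNJ3 higher by 1.61 ± 0.32. Glutamate receptors were higher for 2 and lower for 1 of 19 (4 and 3 adjusted over the list alone, median below 0 and mean above 0), among them GRIK3 by 2.56 ± 0.30 (adjusted p = 1.04e-07). Library 2 gave only 63 satellite glia-like nuclei. At 0.5 times the clustering resolution 4 cholesterol synthesis genes were called. Without the library term edgeR called 4 list genes, with no cholesterol synthesis gene among them, although the median log2 fold of that list was 1.17 (1.14 with the term) and 19 of 20 members lay above 0, and 30 list genes were higher and 29 lower at an unadjusted p under 0.05.

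Macrophage-like nuclei, the resident phagocytes, were set against the mean of the other classes. They were higher in receptors of innate immunity, in MHC class II genes, which present antigen, and in complement genes. Of 367 measured list genes, 60 were higher and 12 lower (n = 2 libraries). Toll-like receptor and inflammasome genes were higher for 11 of 14 (11 adjusted over the list alone; list test adjusted p = 3.55e-14, and adjusted p = 0.00337 with an estimated correlation). MHC class II genes were higher for 8 of 9 (9 adjusted over the list alone; adjusted p = 1.9e-11, and adjusted p = 0.0155 with an estimated correlation), and cytokines and their receptors for 11 of 25 (15 higher and 1 lower adjusted over the list alone; adjusted p = 1.2e-08, and adjusted p = 0.00604 with an estimated correlation).

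TLR2, a receptor of bacterial lipoproteins, was at 110 and 178 CPM in macrophage-like nuclei of libraries 1 and 2 against 13.8 and 31.9 in the other classes, and TLR1 at 25.9 and 56.7 against 4.34 and 6.87. NLRP1 had a log2 fold of 0.35 ± 0.35 (adjusted p = 0.68). CD74, the invariant chain of MHC class II, was higher by 2.12 ± 0.24 (adjusted p = 1.78e-08) and HLA-DMB by 2.49 ± 0.40, while HLA-DMA had 1.06 ± 0.40 (adjusted p = 0.111; called in 1 other setting). IL18, a pro-inflammatory cytokine, was higher by 2.37 ± 0.29 and TNFRSF1B, a receptor of tumour necrosis factor, by 2.50 ± 0.22 (1.89 in library 1 alone), with IL1RAPL1 at -0.16 ± 0.25. Complement genes were higher for 4 of 16 (5 adjusted over the list alone; list test adjusted p = 0.000304, and adjusted p = 0.0281 with an estimated correlation). Chosen after their values were seen, C3, the central complement component, was higher by 2.79 ± 0.19 and ITGAM, a subunit of complement receptor 3, by 3.16 ± 0.29.

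On the CPM scale immediate early genes were higher in macrophage-like nuclei for 4 of 11 (7 adjusted over the list alone; list test adjusted p = 0.000403, and adjusted p = 0.0415 with an estimated correlation), among them DUSP1, a phosphatase of MAP kinases, by 1.92 ± 0.31 and BTG2 by 2.11 ± 0.43. FOSL2 had 0.37 ± 0.24. Per nucleus, macrophage-like nuclei of library 1 held 1.04 UMIs of these genes, below endothelial-like (1.57), satellite glia-like (1.22), fibroblast-like (1.07) and neuron-like nuclei (2.50). In library 2 they held 1.63, the most of these classes, so this order differs between the libraries. SLCO2B1, an organic anion transporter (ENSG00000137491, chromosome 11, 75100563 to 75206549, GRCh38), was higher by 2.89 ± 0.19 (adjusted p = 2.26e-14), and tight junction and transport genes were higher for 4 and lower for 1 of 18 (4 and 1 adjusted over the list alone; adjusted p = 0.0592). KCNK13, a background potassium channel, was higher by 2.93 ± 0.22 (adjusted p = 1.06e-12) and KCNQ3 by 2.36 ± 0.19, and potassium and HCN channels were higher for 5 of 36 (5 adjusted over the list alone; adjusted p = 0.632, median below 0 and mean above 0). TRPM2, a calcium-permeable channel gated by ADP-ribose, was higher by 2.37 ± 0.24, with 4 of 26 sensory transduction channels higher (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.775, median and mean above 0 and the test pointing down). Axon regeneration genes were higher for 4 of 15 (4 adjusted over the list alone; adjusted p = 0.0592), with HIF1A, a transcription factor of the hypoxia response, at 1.65 ± 0.20.

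Collagens and other matrix genes were lower in macrophage-like nuclei for 4 of 32 (4 adjusted over the list alone; list test adjusted p = 0.00126, and adjusted p = 0.116 with an estimated correlation). Tests of neurotrophic factors (adjusted p = 0.00508, and adjusted p = 0.408 with an estimated correlation), axo-glial adhesion (adjusted p = 0.00674, and adjusted p = 0.517 with an estimated correlation) and contractile genes (adjusted p = 0.00361, and adjusted p = 0.345 with an estimated correlation) also pointed down. Without the library term 19 list genes were called.

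**Figure D4:**
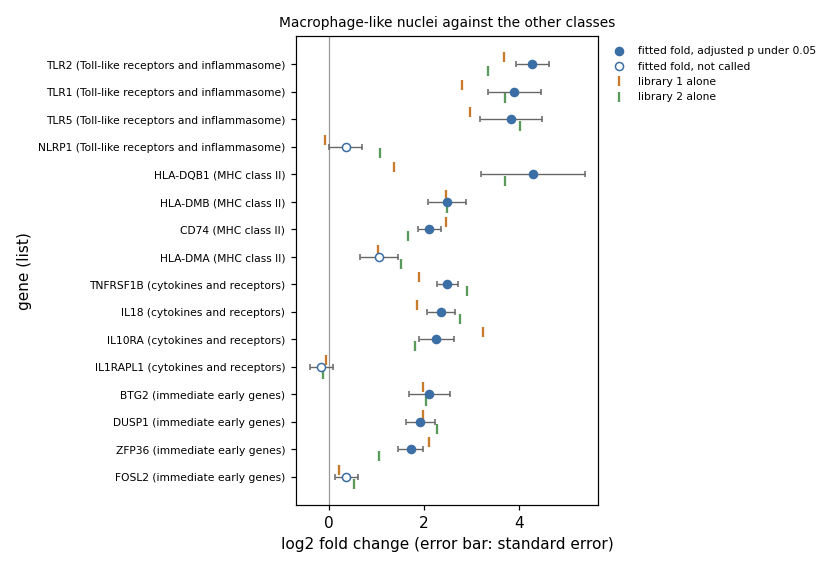
Log2 fold of named genes in macrophage-like nuclei against the mean of the other classes (horizontal axis) by list, with points for the fitted fold, bars for 1 SE, filled points for called genes and ticks for each library alone. CD74 lay at 2.12 and FOSL2 at 0.37, and the fitted folds of TLR1, TLR2, TLR5 and HLA-DQB1 depend on the prior count because the mural-like sums are at 0.

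Fibroblast-like nuclei, the cells that make the connective tissue of the ganglion, were set against the mean of the other classes. They were higher in matrix and complement genes. The class may be mixed with perineurial cells, since 3 other settings gave 313 to 410 perineurial-like nuclei in library 1 and 217 to 273 fibroblast-like nuclei in place of 610. Of 367 measured list genes, 35 were higher and 0 lower by edgeR (n = 2 libraries), with 20 lower at an unadjusted p under 0.05 and 28 higher and 0 lower called by DESeq2, with 19 lower at that unadjusted p. Collagens and other matrix genes were higher for 9 of 32 (13 higher and 1 lower adjusted over the list alone; list test adjusted p = 3.49e-07, and adjusted p = 0.0386 with an estimated correlation). Complement genes were higher for 5 of 16 (7 adjusted over the list alone; adjusted p = 1.78e-07, and adjusted p = 0.0187 with an estimated correlation).

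LAMA2, a laminin chain of basement membranes (ENSG00000196569, chromosome 6, 128883141 to 129516569, GRCh38), was at 3598 and 4290 CPM in fibroblast-like nuclei against 1015 and 999.8 in the other classes, a log2 fold of 2.20 ± 0.20 (adjusted p = 6.18e-10). NID1, nidogen 1, was higher by 1.82 ± 0.20, and COL4A2 had 0.55 ± 0.23 (adjusted p = 0.303). C1R, a complement protease, was higher by 1.42 ± 0.24, and C7 was at 32.8 and 283 CPM against 4.21 and 45.2. CD59 had -0.02 ± 0.22. On the CPM scale immediate early genes were higher for 3 of 11 (7 adjusted over the list alone, list test adjusted p = 0.000155, and adjusted p = 0.0386 with an estimated correlation). JUND was not called (0.63 ± 0.24). Per nucleus, fibroblast-like nuclei of library 1 held 1.07 UMIs of these genes, below neuron-like (2.50), endothelial-like (1.57) and satellite glia-like nuclei (1.22). Macrophage-like (1.04) and myelinating Schwann-like nuclei (0.73) held fewer. In library 2 they held 1.53, and of these classes only macrophage-like nuclei held more (1.63). Cytokines and their receptors were higher for 4 of 25 (6 adjusted over the list alone; adjusted p = 0.00341, and adjusted p = 0.0501 with an estimated correlation), with TGFBR2 at 1.40 ± 0.21 and IL1RAPL1 at -0.14 ± 0.25.

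Tight junction and transport genes were higher in fibroblast-like nuclei for 3 of 18 (3 adjusted over the list alone; list test adjusted p = 0.0425, and adjusted p = 0.22 with an estimated correlation), among them CLDN11, a claudin, by 2.00 ± 0.21. Neurotrophic factors and receptors were higher for 3 of 25 (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.759, median and mean above 0 and the test pointing down). KCNT2 was higher by 1.71 ± 0.20, with 2 of 36 potassium and HCN channels higher (2 adjusted over the list alone; median below 0 and mean above 0), and axon regeneration genes were higher for 2 of 15 (2 adjusted over the list alone). Tests pointed down for calcium channels (adjusted p = 0.0272, and adjusted p = 0.489 with an estimated correlation), sensory transduction (adjusted p = 0.0425, and adjusted p = 0.489 with an estimated correlation), cholesterol synthesis (adjusted p = 0.00669, and adjusted p = 0.455 with an estimated correlation) and axo-glial adhesion (adjusted p = 0.00666, and adjusted p = 0.681 with an estimated correlation). COL4A2 was called in 6 other settings. The calls of the 2 axon regeneration genes ended in 8 and 9 other settings. That of the potassium channel beside KCNT2 ended in 6. Without the library term 4 list genes were called.

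Endothelial-like nuclei, the lining of the vessels, were set against mural-like nuclei, which rest on 32 and 21 nuclei. The mural-like sums held 48494 and 31417 UMIs in libraries 1 and 2, so CPM of single genes in them rest on few UMIs. With the preset correlation only, endothelial-like nuclei were lower in contractile genes. Of 367 measured list genes, 7 were higher and 5 lower (n = 2 libraries). With size factors by median of ratios the split was 3 and 8, and DESeq2 called 0 higher and 10 lower, with 16 higher at an unadjusted p under 0.05. Contractile genes were lower for 2 of 14 (6 adjusted over the list alone; list test adjusted p = 4.84e-22, and adjusted p = 0.0573 with an estimated correlation). MYL9, a regulatory light chain of myosin (ENSG00000101335, chromosome 20, 36541484 to 36551447, GRCh38), was at 15.7 and 27.5 CPM in endothelial-like nuclei against 139 and 261, a log2 fold of -3.20 ± 0.49 (adjusted p = 8.95e-05), and LMOD1, leiomodin 1, fell by 2.62 ± 0.47. PRKG1 had -1.10 ± 0.40 (adjusted p = 0.232; called in 1 other setting).

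Tight junction and transport genes were higher in endothelial-like nuclei for 2 of 18 (4 adjusted over the list alone; list test adjusted p = 0.0161, and adjusted p = 0.103 with an estimated correlation). PLVAP, a protein of the diaphragms of fenestrated endothelium, was at 110 and 102 CPM against 0 in both mural-like sums, and ABCB1, the drug efflux pump P-glycoprotein, at 169 and 355 CPM against 0 and 23.7, with adjusted p-values of 0.146 and 0.204 by DESeq2. At the size of the mural-like sums these values lie near the counting floor, and 0 there does not show absence of a transcript. TACR1, the receptor of substance P, was higher by 2.58 ± 0.53 (adjusted p = 0.00495; 0.145 by DESeq2), and 2 of 12 targets of analgesic drugs were higher (2 adjusted over the list alone; adjusted p = 0.209). Cytokines and their receptors were higher for 1 of 25 (8 adjusted over the list alone; adjusted p = 0.000531, and adjusted p = 0.0587 with an estimated correlation). Calcium channels were lower for 1 of 12 (2 adjusted over the list alone; adjusted p = 6.13e-06, and adjusted p = 0.103 with an estimated correlation). Collagens and other matrix genes were lower for 2 of 32 (2 adjusted over the list alone; median and mean above 0 and the test pointing down), among them COL27A1 by 2.06 ± 0.31 (adjusted p = 6.42e-05), with LAMA2 not called (adjusted p = 1). Without the library term edgeR called 0 list genes, with 31 higher and 12 lower at an unadjusted p under 0.05, and DESeq2 with the term called 10. The comparison exists through the clustering resolution chosen with the class sizes in view, since 6 of 9 resolutions tried gave 16 to 18 mural-like nuclei in library 2 and 20 were needed.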

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

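The value below was picked out after the classes were seen, and no test was run on it. Cluster 11 took no class name in the main setting and entered none of its comparisons. Its 324 nuclei in library 2 held 4117 CPM summed over cholesterol synthesis genes (5119 UMIs). The other 2884 nuclei of that library held 1760 CPM and its satellite glia-like nuclei 3996 CPM. With the lower naming fold this cluster and unnamed cluster 6 (606 and 96 nuclei in libraries 1 and 2) were both named satellite glia-like. That class then held 483 nuclei in library 2 in place of 63. The value stands here because it is a signal in nuclei that the comparisons of the main setting do not use. Cluster 11 held 7 nuclei in library 1, so it may be a feature of library 2. The level of these genes in satellite glia-like nuclei was 1.38 and 2.14 times that in the shallowest unnamed cluster in libraries 1 and 2. No biological explanation was tested.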

How the results depend on the processing

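Alternatives added after the data were seen were nuclei with at least 2000 UMIs, the lower naming fold, neuron-like nuclei without clusters led by genes of other classes, fits without mural-like sums and all settings of the 3 added comparisons; the others were planned. Other scalings for clustering, each library clustered on its own and the mitochondrial limit of 10% were run for class shares only, and no comparison was fitted with them. In the settings fitted, counts of called list genes stayed within 1.5 times the reported count except for the following. With no replicate block, which treats sums of the same library as unpaired, the counts were 62 for A-fibre-like against nociceptor-like, 0 for endothelial-like against mural-like (edgeR; 31 higher and 12 lower at an unadjusted p under 0.05, and 10 called by DESeq2 with the block), 14 for endothelial-like against the other classes, 4 for fibroblast-like, 19 for macrophage-like, 169 for neuron-like, 41 for pruriceptor-like and 4 for satellite glia-like nuclei. DESeq2 called 85 in the A-fibre-like comparison, and 36 were called for satellite glia-like nuclei at 0.5 times the resolution. With an estimated correlation 12 list tests were called in the planned comparisons. The share of nuclei in all named classes, reported as 56.8%, was 75.3% at 0.5 times the resolution, 66.5% at 2 times, 74.3% with called doublets kept, 95.4% with at least 600 genes, 75.9% with each library clustered on its own, 91.2% with genes scaled over all nuclei, 79.7% with the lower naming fold and 51.9% without neuron clusters led by other genes. It was 54.2% to 59.5% in either library alone and 59.5% with the mitochondrial limit of 10%. ERBB3 in endothelial-like nuclei against the other classes reversed to -0.27 with doublets kept (adjusted p = 0.549). The cause of these changes was not tested. In the planned comparisons no call of a named gene was reversed, and called genes keep their direction in either library alone because the naming rule requires it. Of the named and called genes, 24 of 29 stayed called in every setting fitted for neuron-like nuclei, and 26 in every one but the one with no replicate block. These counts were 11 and 20 of 25 for macrophage-like, 4 and 11 of 22 for fibroblast-like, 16 and 17 of 25 for A-fibre-like, 0 and 4 of 8 for endothelial-like against mural-like, 4 and 14 of 24 for satellite glia-like, 9 and 20 of 26 for pruriceptor-like and 9 and 15 of 23 for endothelial-like nuclei against the other classes. Endothelial-like against mural-like nuclei was fitted with the main classes, with the lower naming fold and without the mixed neuron clusters; of the 9 resolutions tried, 3 gave at least 20 mural-like nuclei in both libraries, and only the 1 taken was fitted. Comparisons with non-myelinating Schwann-like nuclei were fitted in 4 other settings, and 6 of the 9 resolutions tried gave that class. In the settings fitted, myelinating against non-myelinating nuclei gave 30 genes higher and 15 lower at 2 times the resolution, 20 and 11 with at least 600 genes, 22 and 14 with the lower naming fold and 16 higher with doublets kept. Satellite glia-like against both Schwann-like classes gave 17 and 16, 11 and 11, 20 and 24, and 25 and 18 in the same order. The pruriceptor-like comparison could not be fitted on separate random parts of the counts, nor this and the satellite glia-like comparison on nuclei with at least 2000 UMIs. In simulation, for genes above the median abundance, 12% of 2-fold changes were found for satellite glia-like and 9% for endothelial-like against mural-like nuclei.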

Other observations

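The comparisons of the first paragraphs were added after the classes were seen, the tests of doublets with neuron nuclei and of larger RNA content were chosen after the result they measure was seen, and the other tests were set before.

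Pruriceptor-like neurons, which resemble the neurons of itch, were lower than nociceptor-like neurons in cholesterol synthesis genes with the preset correlation only (81 and 20 nuclei against 158 and 103). Of 358 measured list genes, 38 were higher and 47 lower in pruriceptor-like nuclei (n = 2 libraries; 41 called without the library term). Cholesterol synthesis genes were lower for 11 of 22 (17 adjusted over the list alone; list test adjusted p = 6.25e-10, and adjusted p = 0.551 with an estimated correlation). GABA-A receptors were higher for 3 of 7 (4 adjusted over the list alone; adjusted p = 7.26e-06, and adjusted p = 0.317 with an estimated correlation), and contractile genes lower for 4 of 11 (5 adjusted over the list alone; adjusted p = 0.031, and adjusted p = 0.551 with an estimated correlation). KCNQ5, an M-current potassium channel, fell by 5.72 ± 0.30 on the log2 scale (adjusted p = 2.01e-13). GRIK4 was higher by 1.90 ± 0.24 and GRIA4, an AMPA receptor subunit, fell by 2.27 ± 0.26. CADM2 was higher by 2.00 ± 0.23 and CNTN1 fell by 2.79 ± 0.27.

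Endothelial-like nuclei against the mean of all other classes were higher for 44 and lower for 4 of 367 measured list genes (n = 2 libraries; 14 called without the library term). TACR1, the receptor of substance P, was at 241 and 335 CPM against 27.6 and 32.9, higher by 3.54 ± 0.21 (adjusted p = 7.22e-16), and CALCRL, a part of the receptor of calcitonin gene-related peptide, was higher by 2.74 ± 0.22 (3.54 in library 1 alone). Targets of analgesic drugs were higher for 3 of 12 (3 adjusted over the list alone; list test adjusted p = 0.002, and adjusted p = 0.27 with an estimated correlation). Tight junction and transport genes were higher for 5 of 18 (5 adjusted over the list alone; adjusted p = 1.19e-06, and adjusted p = 0.0653 with an estimated correlation), among them ABCB1 by 3.11 ± 0.24. Cytokines and their receptors were higher for 7 of 25 (12 adjusted over the list alone; adjusted p = 3e-05, and adjusted p = 0.0448 with an estimated correlation), with TGFBR3 at 1.95 ± 0.19. Chemokines were higher for 3 of 7 (5 adjusted over the list alone; adjusted p = 0.000636, and adjusted p = 0.103 with an estimated correlation). On the CPM scale immediate early genes were higher for 5 of 11 (6 adjusted over the list alone; adjusted p = 0.000636, and adjusted p = 0.0653 with an estimated correlation). Axo-glial adhesion genes (1 of 18 lower, 1 adjusted over the list alone; adjusted p = 0.000636, and adjusted p = 0.43 with an estimated correlation) and calcium channels (1 of 12 lower, 1 higher and 2 lower adjusted over the list alone; adjusted p = 0.00558, and adjusted p = 0.314 with an estimated correlation) pointed down.

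SLC26A3, chosen after its values were seen, had 10906 UMIs (0.0212% of all) in library 1 and 122445 (1.32%) in library 2, where endothelial-like, fibroblast-like, macrophage-like and neuron-like nuclei held 35.9, 32.8, 33.5 and 35.3 UMIs per nucleus.

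Neurofilament transcripts were found in non-neuronal nuclei: NEFL had a UMI in 85.3% and 47.9% of endothelial-like nuclei of libraries 1 and 2 (medians 1648 and 1350 UMIs), against 90.5% and 57.9% of neuron-like nuclei (9227 and 2440 UMIs). Neuron nuclei caught in the same droplets are argued against as the cause, since the ratio of SYT1 to NEFL in the non-neuronal classes was at most 0.0694 times that in neuron-like nuclei. One pool of free RNA stays open, and its prediction was met: the ratio of NEFM to NEFL in the highest of 5 non-neuronal classes was 1.38 times that in the lowest in library 2 and 1.11 times in library 1. The ratio in neuron-like nuclei was 1.35 and 1.02, against 0.956 to 1.07 and 0.50 to 0.688 in these classes. Free RNA may thus be the source of these transcripts, as a hypothesis, and no biological explanation was tested because the labels give 1 group.

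Immediate early genes were lower in neuron-like nuclei for 11 of 11 measured members on the CPM scale. A larger RNA content of neuron nuclei cannot be told apart from lower expression, because the median log2 ratio of UMIs per nucleus was 0.74 in library 1 and -1.53 in library 2. The neuron-like nuclei counted here include the clusters led by genes of other classes. Free RNA is undecided as well. Summed UMIs per nucleus of the highest of 5 non-neuronal classes were 2.16 times those of the lowest in library 1. In library 2 they were 1.65 times. The bounds set beforehand were under 2 in both libraries for free RNA and over 3 in both against it. Only non-neuronal classes enter this test, so it cannot decide the difference from neuron-like nuclei. Both explanations stay open, and the libraries gave different answers. No biological explanation was tested.

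Cholesterol synthesis genes were higher in satellite glia-like than in myelinating Schwann-like nuclei, with a median log2 fold of 1.14. Clusters left without a name are argued against as the cause, since the lowest median over 5 settings, most of which name more clusters, was 0.889, above 0.5 times the value of 1.14. Depth is argued against too, because among nuclei of 1000 to 3000 UMIs the log2 ratio was 0.941 times that over all nuclei in library 1 and 1.05 times in library 2. Free RNA was undecided by the bound of 1.5 set beforehand: satellite glia-like nuclei held 1.38 times the level of the shallowest unnamed cluster in library 1. In library 2 they held 2.14 times. That cluster, taken to stand for free RNA, held 2200 and 1864 CPM. In both libraries this lay between satellite glia-like (3034 and 3996) and myelinating Schwann-like nuclei (1751 and 1073). Free RNA of that level would narrow the difference, so these values argue against free RNA of that level as the cause. This reading was made after the values were seen. Whether the cluster represents free RNA was not tested. Free RNA of another composition was not measured and stays open. A higher level in satellite glia is a hypothesis that these values do not settle, and no biological explanation was tested.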
